A study of Homo sapiens with 8 samples.

How the data were processed

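The data set held 8 single-colour Illumina BeadChip arrays of total RNA from MDA-LM2 cells, in 4 groups of 2 arrays. Groups were read from the sample titles: control siRNA or TARBP2 siRNA, each at 0 h or after 18 h of alpha-amanitin. The arrays of the knock-down groups each carried RNA from 1 of 2 TARBP2 siRNAs. Cells given different TARBP2 siRNAs were separate cultures, but nothing in the labels says so of the control arrays or of independent experiments, so p-values measure only the spread between these arrays, part of which may be technical. No signal was shared by more than 0.33% of probes between replicate arrays, so none was treated as a duplicate.

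The authors deposited non-normalized probe signals, on a linear intensity scale, for 47321 probes, with a detection p-value per probe and array, per the file headers. The lowest intensity on any array was 37.1, and none was negative. The authors deposited a further table of intensity values for the same probes, which the values show to be normalized between arrays, since the sorted values were nearly identical in all 8 columns. The tool lumi is named in the submitters' processing notes without a version, and its settings are not given in the sources used here. The authors also deposited a table of log2 ratios of transcript stability, siTARBP2 over siControl, with 1 value per transcript accession and a class for each (background or stabilized), per the file headers. The formula behind these ratios is not given in the sources used here, and no combination of the array values that was tried gave them exactly. The class was found to be a single threshold on the ratio, at a log2 value of 0.322 (1.25-fold).

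The files do not pair probes with genes. Array results are therefore counts of probes and a few probe identifiers, and named genes come only from the authors' table of ratios. Of its 39745 accessions, 22408 matched 1 symbol in a RefSeq gene table for GRCh38.p14, after removal of version suffixes, and stood for 19465 genes. That table was used for names only. For a gene with several accessions, the mean of their log2 ratios was taken. The level of TARBP2 in each array, the gene-list tests on array data (limma camera and fry), the mean of the probes of a gene and a block for slide could not be run, because probes carried no gene names and the slide is not given in the sources used here.

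Signals were corrected for background and normalized with neqc in limma 3.58.1 (R 4.3.3), which infers the negative controls from the detection p-values, adds an offset of 16 and applies quantile normalization. Probes were kept if their detection p-value was under 0.01 in at least 2 of the 8 arrays, which left 18664. A linear model with 1 coefficient per group was fitted to all 8 arrays, giving 4 residual degrees of freedom, to which eBayes added 2.97 from the other probes. There were 5 contrasts, tested 2-sided: knock-down at 0 h, knock-down at 18 h, the 18 h change in control cells, the 18 h change in knock-down cells, and the difference between these changes, called the stability difference. Probes with a Benjamini-Hochberg adjusted p under 0.05 within a contrast were called. A probe below the detection threshold in both arrays of a group has only a bound there. Its fold is given as "at least", with each such array set at the higher of its own value and the lowest value among the probes it detected, after background correction unless stated. Fits and counts used the normalized values of such probes as they stood.

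Quantile normalization gives every array the same distribution, so each 18 h change is relative to the other transcripts and a global loss of RNA is removed. The number of arrays limits the precision. On simulated arrays with 200 changed probes of 18664, the stability difference recovered 0% of changes of 0.5 log2 units, 82% of changes of 1 and 99% of changes of 2. At 0 h the knock-down contrast recovered 27.5%, 93.5% and 100%. The Benjamini-Hochberg cut is stricter when few probes change, so these shares may understate recovery in the data. Of the 2089 stability-difference calls there, only 129 higher and 68 lower passed 2-fold.

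Before the data were examined, 26 gene lists, the tests on array data, the alternatives and a rule for named genes were fixed. The rule named TARBP2, APP and ZNF395 always, then the 5 largest increases and decreases per comparison, then up to 4 members of each list that passed its test and 3 members of the lists for small RNA machinery and interferon-stimulated genes. It was written for array results, and was carried over to the authors' table after the tables had been seen: the 5 highest and 5 lowest genes, and the members at the end of the list's own direction. For the lists without a call, the 3 members farthest from 0 were taken. Some members that the rule names are not reported here. Each list's median log2 ratio was placed among the medians of 10000 random lists of the same size drawn from the 19465 genes, with pandas 2.3.3 and numpy 2.4.6. This placing replaced the list tests fixed for array data and was chosen after the data had been seen. The random lists were not matched on expression, which that table does not give. No list had a test across replicates, because the table holds a single value per accession.

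The alternatives were scaling by the array median, cyclic loess, the values normalized by the authors, quantile normalization within each time, no background correction, no filter or detection in at least 4 arrays, eBayes with trend and robust, array weights, the compared groups alone, a block for replicate number (over all arrays or within each arm), an adjusted p under 0.1, and leaving out each array in turn. The replicate numbers are those of the siRNAs in the titles.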

Results

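TARBP2 is a double-stranded RNA-binding protein, best known as a partner of Dicer. The experiment asked how its loss changes the stability of transcripts in MDA-LM2 cells, a derivative of the MDA-MB-231 breast cancer line selected for metastasis to the lung. Cells received a TARBP2 siRNA or a control siRNA, and 48 h later RNA was taken at once (0 h) or after 18 h in 10 µM alpha-amanitin, an inhibitor of RNA polymerase II. With synthesis by that polymerase blocked, what remains at 18 h relative to 0 h reflects how stable each of its transcripts is. There were 2 arrays for each of the 4 groups, and in the knock-down groups these carried 2 different TARBP2 siRNAs. The comparison cells are called a control siRNA in the sample titles and mock-transfected in the series text. If they received no siRNA, a response to any siRNA could not be told apart from loss of TARBP2. That would hold for the agreement of the 2 TARBP2 siRNAs as well.

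Between 15541 and 17619 probes were detected per array, or 32.8% to 37.2% of 47321. The upper quartile of the non-normalized signals was 270.2 ± 2.97 (SD, n = 2) in control cells at 0 h and 178.75 ± 6.72 (SD, n = 2) at 18 h. In knock-down cells it was 258.55 ± 10.68 (SD, n = 2) at 0 h and 220.8 ± 1.13 (SD, n = 2) at 18 h. The 2 arrays of a group correlated across probes at r = 0.994 to 0.997. The SD of their log2 difference was highest for control cells at 18 h, at 0.254, and lowest for control cells at 0 h, at 0.171.

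**Figure D1:**
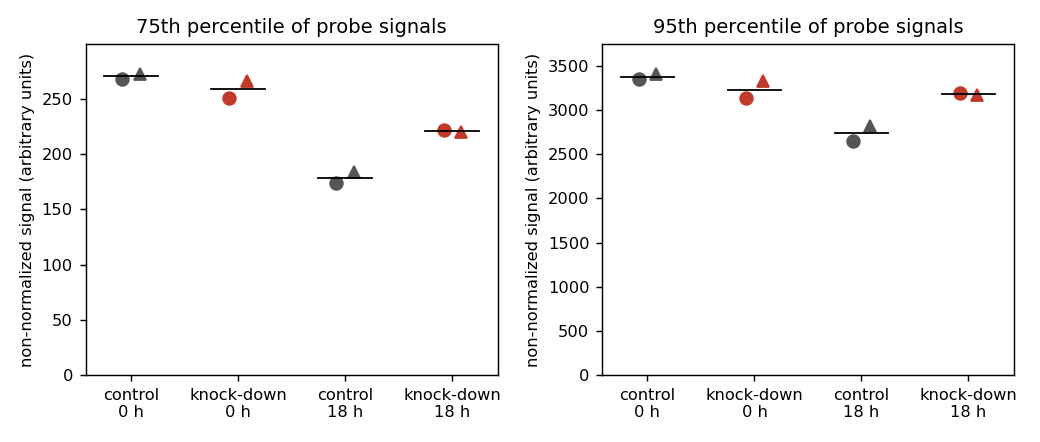
Upper quartile (left) and 95th percentile (right) of the non-normalized probe signals on each array, in arbitrary units, for control (grey) and TARBP2 knock-down cells (red) at 0 h and 18 h. Circles are replicate 1, triangles replicate 2 and lines the group means; the 2 control arrays at 18 h, with upper quartiles of 174 and 183.5, lie below the other 6.

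The level of the targeted gene could not be read from the arrays, because the files do not pair probes with genes. For its stability, the authors' deposited table gives TARBP2 log2 ratios of -0.12 and 0.12 on 2 accessions, neither classed as stabilized. The formula of this ratio of stability is not known. It does not give the level of TARBP2, so it does not check the knock-down.

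Named genes come from the authors' deposited table, which gives 1 stability ratio per accession, knock-down over control, without replicates or a test. Of its 39745 accessions, the authors' deposited table classes 3357 (8.4%) as stabilized by knock-down, all with ratios above 1.25-fold. At the other end, 2508 accessions (6.3%) in the authors' deposited table lie below 0.8-fold. Averaged per gene, 1705 of 19465 genes (8.8%) in the authors' deposited table are above 1.25-fold and 1049 (5.4%) below 0.8-fold.

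The highest ratio in the authors' deposited table belongs to HNRNPL, a regulator of alternative splicing, at 3.41-fold. Among genes matched to a symbol, it is followed in the authors' deposited table by CTNNB1, which encodes beta-catenin, at 3.06-fold (log2 ratio 1.62). SFXN1, a mitochondrial serine transporter, comes after it among these genes in the authors' deposited table, at 2.88-fold. IRF2BPL at 2.81-fold and TRA2A, another splicing regulator, at 2.55-fold complete the 5 highest genes of the authors' deposited table. The lowest gene of the authors' deposited table is CSF2, which encodes the cytokine GM-CSF, at 0.342-fold. Next among genes matched to a symbol in the authors' deposited table are the U6 small nuclear RNA RNU6-1 at 0.407-fold, the cholesterol exporter ABCA1 at 0.448-fold, RPL10L at 0.489-fold and TMEM135 at 0.514-fold. RNU6-1 has many near-identical copies and RPL10L is a near copy of RPL10, so both assignments are uncertain. APP, the amyloid precursor protein gene, has 2 accessions in the authors' deposited table, 1 classed as stabilized with a log2 ratio of 0.42 and 1 as background with 0.14. ZNF395, a zinc-finger gene, is classed as stabilized with a log2 ratio of 0.43 in the authors' deposited table. APP and ZNF395 were fixed in advance because the literature names them as TARBP2-regulated in these cells. Whether that knowledge rests on these same data was not checked, so their ratios are not independent support. In the authors' deposited table, 452 genes have accessions on both sides of the 1.25-fold threshold.

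Genes of mitosis stood highest among the fixed lists. The median log2 ratio of 37 G2/M genes was 0.22 in the authors' deposited table, above all 10000 random lists of that size, with 16 genes above 1.25-fold and 2 below 0.8-fold. Examples from the authors' deposited table are CDCA8, a subunit of the chromosomal passenger complex, at 1.59-fold, the spindle factor TPX2 with a log2 ratio of 0.59, cyclin A2 (CCNA2) at 1.49-fold and the mitotic kinase AURKB at 1.48-fold. The 40 genes of DNA replication and S phase did not share this, with a median of 0.026 at the 50.6th percentile and 4 genes above against 2 below in the authors' deposited table. The difference between these lists was not tested.

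Subunits and general factors of RNA polymerase II, the enzyme that alpha-amanitin blocks, also had high ratios. Their median over 32 genes was 0.20 in the authors' deposited table, above all random lists, with 10 genes above 1.25-fold and 1 below 0.8-fold. The authors' deposited table gives GTF2B, which encodes TFIIB, at 1.42-fold, the TFIIH subunit GTF2H2 at 1.36-fold (log2 ratio 0.45), the polymerase subunit POLR2I at 1.34-fold and CCNT2, a cyclin of P-TEFb, at 1.33-fold as the mean of 2 accessions. Proteasome subunits had a median of 0.12 over 30 genes, at the 97.9th percentile, with 2 above and 0 below in the authors' deposited table. Those 2 are PSMD3 at 1.66-fold and PSMD4 at 1.43-fold, followed in the authors' deposited table by PSMB7 at 1.24-fold and PSMB2 at 1.22-fold.

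Small non-coding RNAs had the lowest ratios. Over 18 of them the median log2 ratio was -0.29 in the authors' deposited table, below all random lists, with 0 above 1.25-fold and 9 below 0.8-fold. Of these, 12 are transcripts of RNA polymerase III, which alpha-amanitin inhibits less, so for them the ratio need not reflect decay. Besides RNU6-1, the authors' deposited table gives the vault RNA VTRNA1-1 at 0.555-fold, RNU11 of the minor spliceosome at 0.607-fold and the Y RNA RNY4 at 0.612-fold. Cholesterol biosynthesis genes had a median of -0.097 over 25 genes, at the 0.68th percentile, with 1 above and 4 below in the authors' deposited table. With the first accession of each gene alone, that median was -0.068 in the authors' deposited table, inside the central 95% of random lists. Among the genes below are SC5D at 0.771-fold and FDPS at 0.794-fold in the authors' deposited table. The 70 nuclear-encoded genes of oxidative phosphorylation had a median of -0.048, at the 0.55th percentile, with 4 above and 7 below in the authors' deposited table. Their lowest members in the authors' deposited table are NDUFC2 at 0.676-fold and NDUFA1 at 0.766-fold, both of complex I, then COX5A and SDHD at 0.790-fold each.

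Of 25 lists with measured members, these 6 lay outside the central 95% of random lists, cholesterol biosynthesis only with accessions averaged or counted singly, against 1.25 expected by chance. The placing among random lists was chosen after the data had been seen, and the expectation takes genes as independent. If the members of a list vary together, more lists would fall outside without any effect of knock-down. TARBP2 partners and small RNA machinery lay inside it, with a median of 0.046 over 24 genes at the 65.6th percentile in the authors' deposited table. None of the 24 gene means passed 1.25-fold or 0.8-fold. The 3 farthest from 0 in the authors' deposited table were AGO2 at 1.23-fold, TSN, which encodes translin, at 0.837-fold, and ADARB1 at 1.19-fold. The ADARB1 value is the mean of 2 accessions, 1 of them classed as stabilized at 1.27-fold. Interferon-stimulated genes had a median of 0.038 over 43 genes at the 62.5th percentile, with 1 above and 3 below in the authors' deposited table. The 3 farthest from 0 in the authors' deposited table were BST2, which encodes tetherin, at 0.546-fold, MX2 at 0.796-fold and OASL at 1.25-fold as the mean of 2 accessions.

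The remaining lists lay within the central 95% as well. Their medians in the authors' deposited table ran from -0.097 for snoRNA host and long non-coding RNAs and -0.077 for endothelial markers to 0.12 for glycolysis. Between these in the authors' deposited table were replication-dependent histones (-0.034), lung metastasis genes (-0.029), ribosomal proteins (-0.022), p53 targets (0.0068), luminal epithelial markers (0.0093), let-7 targets (0.018) and fibroblast markers (0.029). The same holds in the authors' deposited table for ZNF genes (0.033), mRNA decay factors (0.049), extracellular matrix genes (0.054), leukocyte markers (0.062), stress response genes (0.062) and immediate-early genes (0.073). Mitochondrially encoded transcripts had 0 measured members in the authors' deposited table.

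**Figure D2:**
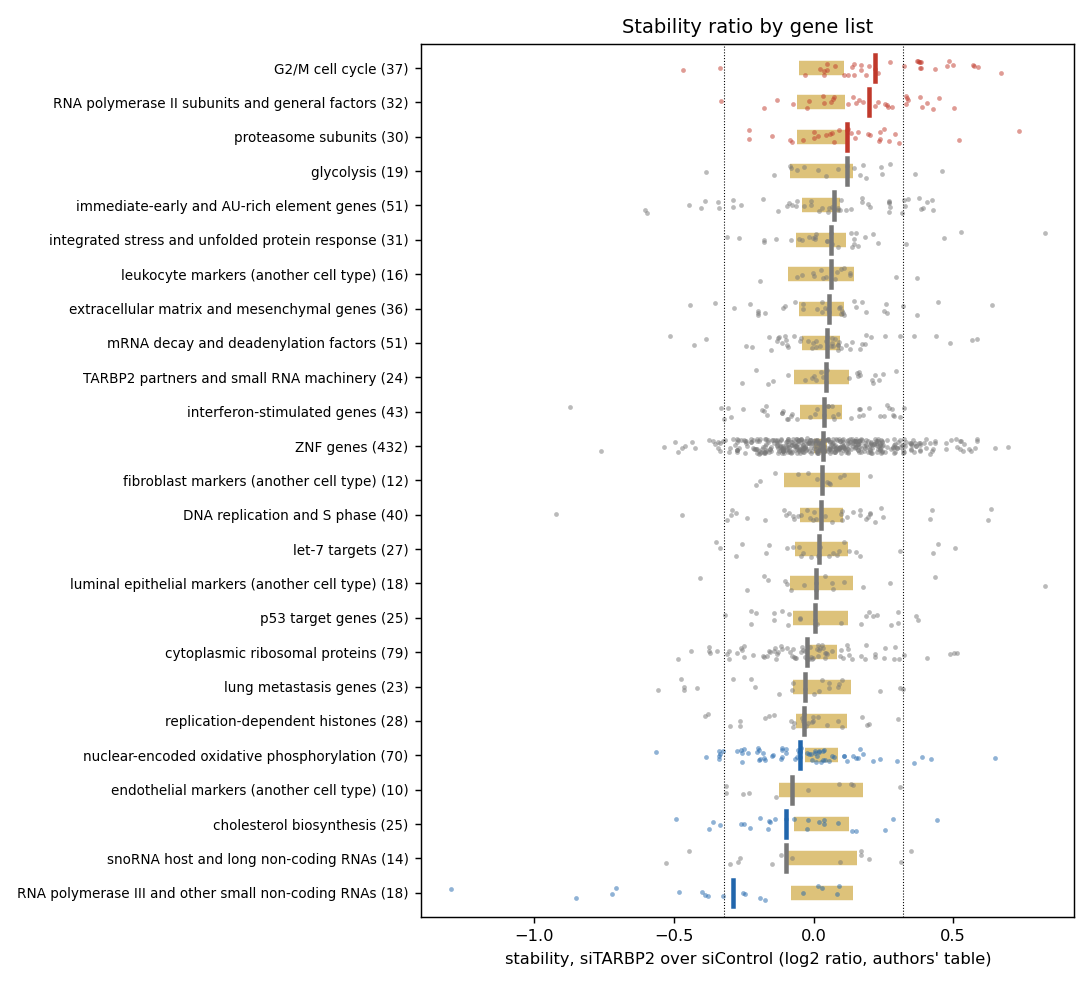
Log2 stability ratio, knock-down over control, of each gene (points) in 25 gene lists, from the authors' deposited table, with the number of genes in parentheses. Thick vertical marks are list medians (red above, blue below, grey within the central 95% of random lists, drawn as bars), and dotted lines mark 1.25-fold and 0.8-fold; G2/M genes have the highest median, 0.22, and small non-coding RNAs the lowest, -0.29.

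On the arrays, the stability difference asks for which probes the 18 h change differed between knock-down and control cells. Of 18664 detected probes, 2089 (11.2%) differed by limma's test, 1159 higher and 930 lower in knock-down cells, and 129 and 68 of these by over 2-fold. Most kept their direction in both arms: 1250 rose in both or fell in both, to different extents. A further 93 rose in knock-down cells and fell in control cells, 82 did the reverse, and 664 were called in at most 1 arm. Probe ILMN_2389582 fell below detection in control cells, from a log2 value of 7.64 ± 0.040 to 5.19 ± 0.17 (SD, n = 2), and was 6.86 ± 0.044 at 0 h and 7.05 ± 0.031 at 18 h in knock-down cells (SD, n = 2). Its stability difference was at least 3.34-fold higher (at least 2.21-fold without background correction; limma adjusted p = 0.00329). For ILMN_1746396 the difference was 2.37 ± 0.14 (log2, SE; limma adjusted p = 0.00355). In the other direction, ILMN_1661861 was at least 4.32-fold lower (2.55-fold without background correction; limma adjusted p = 0.00637) and ILMN_1782939 at least 2.60-fold lower (1.94-fold; limma adjusted p = 0.00355). ILMN_1782939 rose in both arms, in control cells from a mean log2 value of 5.25, below detection, to 9.48. In knock-down cells it rose from 6.60 to 8.92, so its difference need not reflect decay.

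The direction of these calls depended on scaling. With arrays scaled by their median, 5195 probes were called, 4766 higher and 429 lower (91.7% higher, against 55.5%), and the median stability difference shifted by 0.212 on the log2 scale. Single arrays also mattered: the count was 306 or 173 without either knock-down array at 0 h, 153 or 208 without either at 18 h, 76 or 53 without either control array at 0 h, and 1363 without replicate 2 of the control arrays at 18 h. With a block for replicate number within each arm it was 0, with a lowest limma adjusted p of 0.053 and 5208 probes at an unadjusted p under 0.05.

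**Figure D3:**
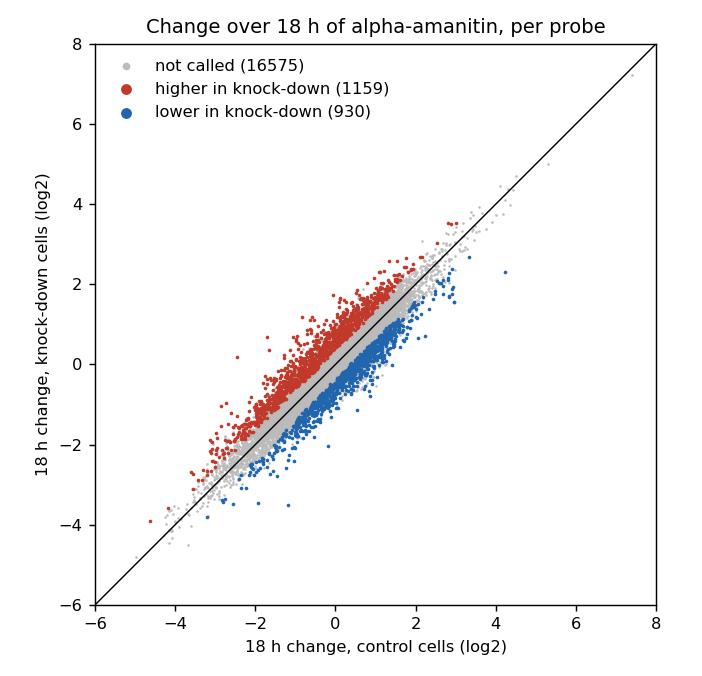
Log2 change over 18 h of alpha-amanitin in control cells (x axis) and in knock-down cells (y axis) for each of 18664 detected probes, with the line of equal change. Red points are the 1159 probes with a higher and blue points the 930 with a lower change in knock-down cells by limma's test; most points lie along the line (r = 0.935).

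The relative level of most transcripts changed over 18 h in alpha-amanitin in either arm. The drug and the 18 h in culture go together in these arrays, so their effects are not separated. In control cells 14500 probes (77.7%) changed over 18 h, 7679 higher and 6821 lower, and in knock-down cells 14211 (76.1%) changed, 7530 higher and 6681 lower. Over 4-fold, 714 probes fell and 248 rose in control cells, and 648 fell and 274 rose in knock-down cells. The largest increase, on the same probe in both arms, was 168-fold in control cells (limma adjusted p = 2.89e-07) and 150-fold in knock-down cells (limma adjusted p = 3.38e-07), relative to other transcripts. The changes of the arms, which share no array, correlated across probes at r = 0.935 (Spearman 0.921), and 88.8% of probes had the same sign; probes are not independent replicates. In both arms 6509 probes rose, where independent lists would share 3098.1, and 5889 fell, where they would share 2441.7. These directions are relative as well. Scaled by the array median, 29.9% of the calls were higher in control cells (against 53%) and 39.8% in knock-down cells, with medians shifted by -0.445 and -0.234. Under cyclic loess the medians shifted by -0.145 and -0.12.

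Before transcription was blocked, knock-down had a small effect on transcript levels. At 0 h, 754 probes (4%) differed between knock-down and control cells, 399 higher and 355 lower, of which 5 and 9 passed 2-fold. ILMN_1729767 fell below detection in knock-down cells and was at least 4.66-fold lower (2.79-fold without background correction; limma adjusted p = 0.000258). ILMN_1782939 was below detection in control cells and at least 1.77-fold higher after knock-down (1.37-fold; limma adjusted p = 0.00374). Scaled by the array median, 314 of 782 calls were higher (40.2%, against 52.9%). The count fell to 32 or 16 without either knock-down array at 0 h, 241 or 250 without either at 18 h, and 6 or 5 without either control array at 0 h.

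After 18 h in alpha-amanitin the arms differed more. At that time 5363 probes (28.7%) differed, 2898 higher and 2465 lower in knock-down cells, with 88 and 89 over 2-fold. ILMN_2389582 was at least 1.95-fold higher (1.51-fold without background correction; limma adjusted p = 0.000398) and ILMN_1661861 at least 6.30-fold lower (3.61-fold; limma adjusted p = 0.000398). Some probes were called at both times: 155 were higher at 0 h and 18 h, where independent lists would share 62, and 177 were lower, where they would share 46.9. The knock-down effects at the 2 times share no array and correlated across probes at r = 0.190. Scaled by the array median, 8106 probes were called at 18 h, 86% of them higher (against 54%), with the median shifted by 0.184. The count was 2569 or 2442 without either knock-down array at 18 h.

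The 2 TARBP2 siRNAs gave related effects. With each siRNA set against a different control array, their effects correlated across probes at r = 0.497 (Spearman 0.475) at 0 h, 0.632 (0.645) at 18 h and 0.532 (0.546) for the stability difference. The same sign was seen for 67.4%, 75.9% and 71.1% of probes. These are descriptions over probes, since each siRNA was measured on 1 array per time.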

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

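The slopes in both directions, the SD ratio and the tests against a curve of the control change were chosen only after the changes of the arms had been seen, and the bound on the count of probes called against the curve only after those counts; the other tests here were written down before their results.

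The 18 h change differed between knock-down and control cells for 2089 probes by limma's test of the interaction, and 175 of these probes were also called in opposite directions in the 2 arms. The 2089 probes bear on whether TARBP2 loss alters transcript stability only where the 18 h change reflects decay. Of them, 311 with a higher and 282 with a lower difference rose in both arms, relative to other transcripts. For those the change need not be decay. None of the probes has a gene name here.

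Whether the 18 h changes were smaller in knock-down cells as a whole is not settled. The slope of knock-down on control changes, estimated with separate arrays for each term, was 0.936, and lay between 0.917 and 0.958 in all 20 estimates over 5 scalings. The reverse slope, of control on knock-down changes, was below 1 as well, at 0.972, because differences between the arms on single probes lower both. The SD of the changes shared by the replicates of an arm was 0.982 times as large in knock-down as in control cells, and 0.971 to 0.997 times over the 5 scalings. The highest slope, 0.952 under cyclic loess, therefore decides nothing about normalization.

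A uniformly weaker block of transcription in knock-down cells, with decay otherwise alike, would make the 18 h change in knock-down cells a single curve of the change in control cells. Against a smooth curve, fitted over probes within each of 10 bins by signal so that it also absorbs array factors, 1606 to 2338 probes were called over the 5 scalings, 1178 to 2071 of them among the stability-difference calls of the same scaling and the rest new, with 865 to 1245 above the curve and 741 to 1093 below it. On simulated arrays where the knock-down change was 0.8 times the control change, 157 probes had a stability difference and 0 were called against the curve. The simulated arrays held no other difference between the arms, so they show only that the curve test made no false calls in that case. The calls argue against a uniformly weaker block as the source of all the called differences, on the premise that each 18 h change reflects decay. Probes that rose in both arms need not meet that premise, and the counts did not set them apart. For the calls that the curve removed, a weaker block stays open. The share of stability-difference calls left was 0.706 with the main scaling, 0.227 with array-median scaling (5195 calls, 4766 of them higher) and 0.139 with non-normalized signals (8665 calls), where a share under 0.1 or of at least 0.2 in every scaling would have decided. Other values go both ways. The upper quartile of non-normalized signals fell from 270.2 to 178.75 in control cells and only from 258.55 to 220.8 in knock-down cells, as with a weaker block. The 95th percentile in control cells fell by a smaller share, from 3375.1 to 2732.95, so 1 factor per array would not give both falls. Array effects that change with signal level were not separated from a weaker block. Quantile normalization removes such shifts. With non-normalized signals, the stability difference was positive for 83% to 95.6% of probes in the bins that fell in control cells, but also for 69.2% to 85.2% in the bins that rose; with the main scaling the shares were 53.1% to 65.4% and 39.3% to 47.2%. Short-lived transcripts did not decide either: immediate-early genes lay at the 91.1st percentile of random lists and ZNF genes at 73.4 (73.43), where only positions below 50 or in the top tail of random lists would have decided.

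That stabilized transcripts were already higher before the block also stays open. The stability difference correlated with the knock-down effect at 0 h at -0.167 to -0.146 with no shared array, where a value at or below 0 had been set in advance to exclude it. That bound was wrong, although the sign of the correlation was not fixed in advance. The 0 h effect enters the stability difference with a negative sign. Any part of it that was gone by 18 h therefore lowers the correlation, so a negative value does not exclude such transcripts. The 0 h and 18 h effects themselves correlated at 0.142 to 0.157. A biological difference between the arms in decay or in response to alpha-amanitin was not separated from these.

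The spread between the replicate arrays of a group was argued against as the source of all the stability differences above 1.25-fold. A contrast of replicates 1 against replicates 2, which holds no knock-down effect common to the siRNAs, put 940 probes above 1.25-fold, against 3307 for the stability difference, a ratio of 0.284. Any deviation that both arrays of a group share, as from a common culture or batch, is absent from that contrast. It would enter the stability difference, so it is not argued against. With the values normalized by the authors, over all 47321 probes, the shares were 3.5% and 8.2%, so a ratio above 1.25-fold on a single transcript could still be noise. That holds most for probes left out as undetected, where the shares were 4.7% and 5.5%.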

How the results depend on the processing

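The counts of 18 h changes stayed within 1.5 times under each alternative run for them. Their Pearson correlation between arms stayed within 0.05 with array-median scaling, the values normalized by the authors, no filter and each array left out. Without a filter its Spearman value was 0.694 and the same sign was seen for 69% of probes. Knock-down at 0 h (754) gave 1149 with the values normalized by the authors, 1360 without background correction, 128 without a filter, 2012 with trend and robust, 303 with the compared groups alone and 1809 at an adjusted p under 0.1. Knock-down at 18 h (5363) gave 8106 with array-median scaling, 3360 without a filter and 3081 with the compared groups alone. The stability difference (2089) gave 5195 with array-median scaling, 389 without a filter, 3595 with trend and robust and 4005 at an adjusted p under 0.1. Without a filter 47321 probes were tested, most of them at background; the cause of the other shifts was not tested.

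In the knock-down arm the replicate number names the siRNA, so by the titles it links the 0 h and 18 h arrays there. No component shared by same-numbered arrays was seen: deviations from the group means correlated at -0.035 to 0.026 between them. With the replicate block the counts were 304 at 0 h and 1363 for the stability difference; with the block within each arm the stability difference had 0, the fit losing residual degrees of freedom. The block changed no other count by over 1.5 times. Leaving out each array in turn gave 5 to 651 calls at 0 h, 2442 to 4821 at 18 h and 53 to 1522 for the stability difference; the lone array left in a group is assumed to vary like the others.

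The correlation of the siRNAs at 0 h was 0.561 with the values normalized by the authors and 0.269 without a filter. At 18 h it was 0.702 with array-median scaling, 0.696 with the values normalized by the authors and 0.434 without a filter. For the stability difference it was 0.588 and 0.322 under the latter pair.

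Of 400 recomputed values of probes with the largest changes, 391 kept direction and call, 9 lost the call and 0 reversed. Folds moved more: the bound of 6.30-fold for ILMN_1661861 at 18 h was 3.61-fold without background correction, that of 4.66-fold for ILMN_1729767 at 0 h was 2.79-fold, and the 5.18-fold difference of ILMN_1746396 was 3.81-fold. Of 50 recomputed list positions, chosen after the data were seen, 48 were unchanged: ribosomal proteins moved below the central range with every accession counted (-0.03), and cholesterol biosynthesis moved into it with the first accession of each gene (-0.068). Signal over background limits dim probes: bounds were set only for the probes named, and counts used the fitted values.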

Other observations

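Every gene named in the first 2 paragraphs was chosen after its value was seen, as were the gene lists that the splicing and small-RNA comparisons use; the tests on signal level and on splicing regulators were written down before their results.

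Of 23 lung metastasis genes, 5 lie below 0.8-fold and 0 above 1.25-fold in the authors' deposited table, with the list median (-0.029) at the 14.3rd percentile of random lists. Those 5 are, in the authors' deposited table, the collagenase MMP1 at 0.680-fold, LY6E at 0.720-fold, the interleukin-13 receptor IL13RA2 and the matrix protein SPARC at 0.725-fold each, and ANGPTL4 at 0.749-fold. The highest of the list in the authors' deposited table, EREG and IL11, have log2 ratios of 0.3213 and 0.3093, just under the threshold of 0.322.

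Unstable transcripts went both ways. Among 51 immediate-early and AU-rich element genes, 9 lie above 1.25-fold and 7 below 0.8-fold in the authors' deposited table. The phosphatase DUSP1 at 0.659-fold, the kinase SGK1 at 0.662-fold and the cytokine LIF at 0.735-fold were lowest in the authors' deposited table, and the decay factor ZFP36L2 at 1.34-fold (log2 ratio 0.43) and CCN1 at 1.34-fold highest. Among stress response genes the authors' deposited table puts DDIT3, which encodes CHOP, at 1.77-fold (log2 ratio 0.83), its target TRIB3 at 1.44-fold and VLDLR at 1.38-fold, with 4 genes above 1.25-fold and 0 below 0.8-fold.

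The list medians could follow from the signal level of their transcripts if bright and dim probes differed in stability. With the values normalized by the authors, over 10 bins of detected probes by mean signal, the median stability difference lay at most 0.0562 from 0, in the dimmest bin. A bound of 0.1 had been set in advance to argue against signal level, but it was wrong: those values have nearly the same distribution on all arrays, which itself holds such medians near 0, and the signal of the listed transcripts is not known. Signal level stays open for every list. Within the small RNAs, 12 transcripts of RNA polymerase III, which alpha-amanitin inhibits less, had a median of -0.32 and 6 small nuclear RNAs of RNA polymerase II a median of -0.28 in the authors' deposited table, so the low ratios were not limited to either polymerase's products. A biological explanation for the list differences was not tested.

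With HNRNPL and TRA2A among the 5 highest genes, splicing regulators might be stabilized as a group. The other 33 SR proteins, hnRNPs and relatives had a median of 0.066, at the 81.1st percentile of random lists (81.1), with 5 above and 2 below in the authors' deposited table, where only a position below 50 or in the top tail would have decided.

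The arrays of the 2 TARBP2 siRNAs differed about as much as the 2 control arrays at 0 h, and less at 18 h. The SD of the difference between the siRNAs over that between the controls was 1.07 at 0 h and 0.755 at 18 h. The labels do not say whether the 2 control arrays are replicates or 2 control siRNAs. A fit for a difference common to 0 h and 18 h, with each siRNA on 1 array per time, called 0 probes by limma (717 at an unadjusted p under 0.05), and 0 between the controls (958). It does not show that the siRNAs act alike: on simulated arrays that fit recovered 0% of differences of 0.5 log2 units, 94.5% of differences of 1 and 100% of differences of 2, and it does not see a difference at only 1 of the times.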
